A study of Mus musculus with 90 samples.

How the data were processed

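RNA of 4 tissues of male mice (BAT, iWAT, muscle and hypothalamus) from 4 genotypes was sequenced by the authors as stranded poly(A) libraries with paired reads of 100 bp. Per the submitters' processing notes, reads were aligned with STAR to the mouse genome build mm10 and counted per gene with HTSeq; the tool versions are not given in the sources used here. The deposited values are raw counts per gene: whole numbers, 1 file per library, 90 libraries. Group and tissue were taken from the labels. The labels carry no replicate numbers and do not say which libraries share a mouse, so replicate numbers follow the order of the deposit, tissues were fitted separately and no paired test was made.

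Each file held 32765 rows. In 66 cases a name occurred a second time after trimming of spaces, and the counts were summed; 32697 gene rows were kept. Of these 8427 carry a sequence accession as name (4.96% to 22.6% of the counts of a library), and 24275 names matched a symbol or unique synonym of the reference gene table (GRCm38). Of the rows 2 name no single gene and held at most 0.22% of the counts of a library. The 10 most abundant genes took 5.89% to 30.7% of the counts. Total counts (1 M is 1e6) ranged from 34.8 to 57.3 M in BAT, 36.5 to 54.1 M in iWAT, 18.1 to 61 M in muscle and 35.5 to 69.9 M in hypothalamus. Over 210 pairs of replicates the chi-squared statistic per degree of freedom ran from 3.63 to 713 (genes with at least 20 counts in the pair), so replicates differ by more than counting error.

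In each tissue, counts were fitted with edgeR 4.0.16 (R 4.3.3): TMM normalization, the low-count filter of filterByExpr on genotype, robust quasi-likelihood dispersions and the quasi-likelihood F test. This left 16032 genes in BAT, 16751 in iWAT, 15120 in muscle and 18020 in hypothalamus, with biological coefficients of variation of 0.257, 0.388, 0.101 and 0.093. TMM factors ran from 0.815 to 1.28 in BAT, 0.821 to 1.38 in iWAT, 0.944 to 1.04 in muscle and 0.989 to 1.01 in hypothalamus. The contrasts were UCP1 KO against WT, FGF21 KO against WT, dKO against WT, dKO against UCP1 KO and the interaction of both knockouts; dKO against FGF21 KO served for the sign comparison and the windows around the targeted genes. A gene was called at a Benjamini-Hochberg (BH) adjusted p under 0.05 over the genes tested in that tissue and contrast, and all adjusted p in the text are BH values. The standard error of a log2 fold change is its size divided by the square root of F. Levels are CPM with TMM library sizes from the tested genes; values per library and ranges over libraries use TMM on all genes, which differ slightly.

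The 39 gene lists were written before the data were examined and tested in the tissues each was written for, with camera (limma 3.58.1) at a preset correlation of 0.01, BH over the lists of a tissue and contrast, and again with the correlation estimated per list. Lists with fewer than 5 measured genes were not tested. The 13 mitochondrially encoded subunits in 1 list had no rows in the files. For each list, calls were also counted after BH over its own members ("adjusted over the list alone"). Called genes within 10 Mb of Ucp1 or Fgf21 were compared with called genes elsewhere by a two-sided Fisher's exact test.

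Genes were named by a rule written before the data were examined: Ucp1 and Fgf21 in every tissue; per tissue and contrast up to 6 called genes per direction with the largest fold changes among those with a mean of at least 1 CPM and no overlap between the groups; in each list the called member with the smallest p in each direction, or 2 per direction for a list past camera; up to 6 genes called in the same direction in all 4 tissues; and Fgf12, Nnt, Xist and Ddx3y. The fits and camera were tested on simulated data with 200 genes changed 1.5-fold, 2-fold or 4-fold in either direction. No called gene had the wrong sign.

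The alternatives fixed before the data were examined were DESeq2 1.42.0, RLE size factors, no low-count filter, fits with the compared groups alone, Ucp1 and Fgf21 left out of the library sizes, genes near the targeted loci left out, each library left out in turn, an estimated correlation for the lists, and windows of 5 and 20 Mb. Added after seeing the data were a covariate for genes of other tissue and fits without the libraries in which such genes lay high (mean log2 CPM over 7 for muscle genes in BAT, over 2 for lymphocyte genes in iWAT and over 3 for choroid plexus genes in hypothalamus). Each comparison was also fitted to 100 splits of its samples, the real one included. Figures were drawn with matplotlib 3.10.9.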

Results

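RNA was measured by poly(A) sequencing in 4 tissues of male mice kept in the cold: brown adipose tissue (BAT, the depot specialised for heat production), inguinal white adipose tissue (iWAT, a subcutaneous fat depot that can take on brown-like features), muscle and hypothalamus. The mice were wild type (WT), lacked uncoupling protein 1 (UCP1 KO), lacked fibroblast growth factor 21 (FGF21 KO) or lacked both (dKO). UCP1 is the mitochondrial carrier that lets brown fat turn fuel into heat, and FGF21 is a hormone of the FGF family. The series asks what each gene contributes to metabolism in the cold. All mice were reared at 30 °C, moved at 10 to 12 weeks of age to 18 °C for 12 days, and then held at 5 °C for 3 weeks. The 90 libraries fell into 16 groups. WT, UCP1 KO, FGF21 KO and dKO held 5, 6, 5 and 6 libraries in BAT, 6, 6, 5 and 6 in iWAT and in muscle, and 6, 6, 5 and 5 in hypothalamus. Total counts per library ranged from 18.1 to 69.9 M (1 M is 1e6 counts) with a median of 46 M. The labels do not say which libraries came from the same mouse, although the protocol gives 5 to 6 mice per genotype, so the p-values rest on the spread between the labelled samples.

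Ucp1 lies on chromosome 8 from 83290348 to 83298456 and Fgf21 on chromosome 7 from 45613890 to 45615490 (GRCm38). In BAT, Ucp1 stood at 8524 ± 1350 counts per 1e6 counts (CPM; mean ± SD, n = 5) in WT and 1139 ± 192 (n = 6) in UCP1 KO, a log2 fold change of -2.90 (SE 0.12, adjusted p = 5.05e-14). It stood at 11200 ± 397 (n = 5) in FGF21 KO and 1354 ± 143 (n = 6) in dKO, so every library labelled UCP1 KO or dKO lay below every library with intact Ucp1. In iWAT the counts at Ucp1 ran the other way: 516 ± 406 CPM (n = 6) in WT, 588 ± 348 (n = 5) in FGF21 KO, 1421 ± 278 (n = 6) in the libraries labelled UCP1 KO and 1330 ± 326 (n = 6) in dKO. The log2 fold change for UCP1 KO against WT in iWAT was 1.46 (SE 0.63) with an adjusted p of 0.0622. In iWAT FGF21 KO replicate 5, Ucp1 stood at 6.83 CPM, and in the other libraries of that group at 550 to 890 CPM. Counts per gene do not show which exons remain in the knockout transcript, so Ucp1 counts alone do not check the genotype labels in iWAT. In hypothalamus, Ucp1 stood at 1.83 ± 1.14 CPM (n = 6) in WT and 4.79 ± 0.87 (n = 6) in UCP1 KO, and in muscle at 1.60 ± 0.974 (n = 6) and 2.78 ± 1.02 (n = 6), and neither difference passed the test.

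Fgf21 RNA was low in WT adipose tissue, with 8 to 67 counts per library in BAT and 9 to 26 in iWAT, and rose with loss of UCP1. In BAT it went from 1.01 ± 0.622 CPM (n = 5) to 30.2 ± 10.4 (n = 6), a log2 fold change of 4.91 (SE 0.54, adjusted p = 1.9e-07). In iWAT it went from 0.383 ± 0.131 (n = 6) to 22.5 ± 9.32 (n = 6), a log2 fold change of 5.87 (SE 0.42, adjusted p = 4.38e-09). In dKO it stood at 0.0071 ± 0.0114 CPM in BAT and 0.037 ± 0.0319 in iWAT (n = 6 each), lower than in UCP1 KO with adjusted p = 1.99e-07 and 6.17e-10. In FGF21 KO it stood at 0.101 ± 0.169 CPM in BAT and 0.00439 ± 0.00983 in iWAT (n = 5 each). The difference from WT passed the test in iWAT (adjusted p = 0.000331) and missed it in BAT (log2 fold change -3.34, adjusted p = 0.172). In BAT FGF21 KO replicate 4 held 13 Fgf21 counts (0.4 CPM), more than the 8 of WT replicate 3 (0.171 CPM), and the other 4 FGF21 KO libraries held 0 to 2. Without this library the log2 fold change in BAT was -5.06 (adjusted p = 0.0386). Mean Fgf21 reached at most 0.0165 CPM in any muscle group and 0.0389 CPM in any hypothalamus group. Fgf12, which the series text names once in place of Fgf21, stood at 188 ± 12.3 CPM in WT hypothalamus and 190 ± 15.5 in dKO (log2 fold change 0.02, SE 0.05). The X-linked transcript Xist stayed at or below 0.276 CPM and the Y-linked Ddx3y at or above 76.6 CPM in all 90 libraries.

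**Figure D1:**
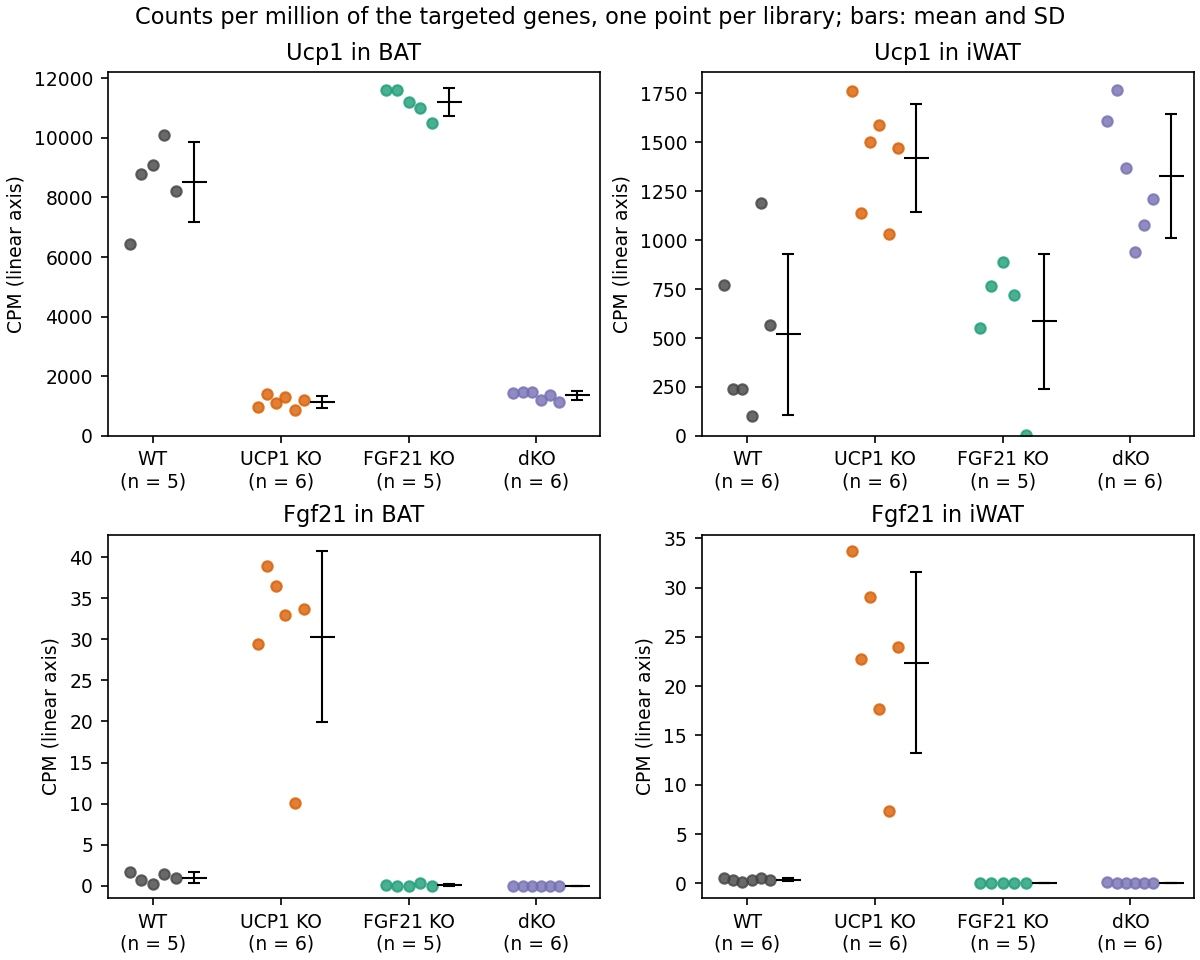
CPM of Ucp1 and Fgf21 in each library of BAT and iWAT (linear axis; points are libraries, bars are mean and SD). BAT Ucp1 separates the knockouts (means of 1140 and 1360 CPM, all genes kept) from WT (8520 CPM), whereas Fgf21 is high in UCP1 KO alone, with means of 30.3 CPM in BAT and 22.4 CPM in iWAT.

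Fuel-handling genes mostly fell in UCP1 KO BAT. All 18 measured genes of lipogenesis and triglyceride synthesis passed the test. Of these 17 fell and Dgat1, which makes triglyceride, rose by 0.45 log2 units (SE 0.09). Acacb, an acetyl-CoA carboxylase, went from 3082 ± 140 (n = 5) to 879 ± 166 CPM (n = 6; log2 fold change -1.81, SE 0.10, adjusted p = 5.82e-12). Likewise Mlxipl, the carbohydrate-responsive transcription factor ChREBP, went from 717 ± 82.8 to 166 ± 30.4 CPM. Of 22 glucose uptake and glycolysis genes 13 fell, among them Hk2 (-1.91, SE 0.12) and Pkm (-1.37, SE 0.08), and 2 rose, Slc2a1 (1.45) and Hk1 (0.30). Of 17 cholesterol synthesis genes 13 fell and none rose, with Fdft1 at -2.00 (SE 0.11). Of 51 nuclear-encoded respiratory chain and ATP synthase genes 42 fell and none rose, by a smaller median of -0.31. Sdha went from 3580 ± 200 to 2183 ± 142 CPM (-0.71, SE 0.06). Of 17 citric acid cycle genes 12 fell, led by Suclg2 (-1.09) and Pdha1 (-1.34), and 1 rose, the citrate synthase gene Cs (0.33).

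The median log2 fold changes of these BAT lists were -1.48 for lipogenesis, -1.07 for glycolysis, -0.86 for cholesterol synthesis and -0.37 for the citric acid cycle. All 5 lists passed camera, with adjusted p = 2.47e-07 for lipogenesis and for glycolysis, 2.75e-05 for cholesterol synthesis, 5.54e-07 for the respiratory chain and 8.37e-05 for the citric acid cycle. None of the 5 calls held with an estimated correlation: adjusted p = 0.434 for lipogenesis, cholesterol synthesis and the citric acid cycle, 0.131 for glycolysis and 0.501 for the respiratory chain. Adjusted over the list alone, the counts were 1 higher and 17 lower for lipogenesis, 2 and 13 for glycolysis, 0 and 13 for cholesterol synthesis, 0 and 42 for the respiratory chain, and 1 and 13 for the citric acid cycle. The 24 brown and beige adipocyte genes did not move one way. Of these 10 rose, among them Fabp3 (442 ± 41.1 to 1337 ± 58.7 CPM), 9 fell, among them Acot11 (2004 ± 240 to 472 ± 120 CPM). Camera gave an adjusted p of 0.88 (median 0.00, mean 0.20; 11 higher and 9 lower adjusted over the list alone). Fatty acid oxidation genes split into 13 lower, such as Echs1 (-0.70), and 2 higher, such as Cpt1a (2.12, SE 0.10), which lets long fatty acids into mitochondria (20 measured, camera adjusted p = 0.346; 2 and 13 adjusted over the list alone). Lipolysis and lipid droplet genes split 4 and 5 of 15 over all genes and adjusted over the list alone, with Lpl at 1.06 and Plin4 at -1.01 (median 0.07, mean -0.02, adjusted p = 0.771).

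Genes of the amino acid and ATF4 stress response rose in BAT, a list of amino acid uptake and synthesis genes that the transcription factor ATF4 turns on. Of 24 measured members 20 rose and none fell (21 and 0 adjusted over the list alone), with a median log2 fold change of 2.34 and a camera adjusted p of 1.37e-25. This call held with an estimated correlation (adjusted p = 7.08e-06). The amino acid transporter gene Slc7a5 went from 0.653 ± 0.221 (n = 5) to 22.8 ± 4.0 CPM (n = 6; log2 fold change 5.13, SE 0.21, adjusted p = 1.34e-13) and Aldh18a1, of proline synthesis, from 3.01 ± 0.429 to 25.2 ± 6.66 CPM (3.07, SE 0.15). Of 16 endoplasmic reticulum chaperone genes 12 rose and none fell (12 and 0 adjusted over the list alone), with Hspa5, the chaperone BiP, at 0.96 (SE 0.09) and Edem1 at 0.83 (SE 0.07). Their median was 0.35 with a camera adjusted p of 0.00276, and adjusted p = 0.434 with an estimated correlation. Heat shock genes split into 3 higher, such as Hspd1 (0.43), and 4 lower, such as Hsp90ab1 (-0.69), of 13 (adjusted p = 0.581; 3 and 4 adjusted over the list alone).

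Genes of immune cells and of dividing cells were higher in UCP1-deficient BAT. Of 21 macrophage genes 19 rose and none fell. C1qa, a complement component, went from 17.9 ± 1.63 (n = 5) to 84.4 ± 13.2 CPM (n = 6; log2 fold change 2.24, SE 0.12, adjusted p = 3.36e-12), and C1qc rose by 2.19 (SE 0.13). Of 16 interferon-stimulated genes 15 rose, with the antiviral gene Mx1 at 4.54 (SE 0.41) and Rtp4 at 1.81 (SE 0.20). Of 16 lymphocyte genes 12 rose, including Cd4 (0.745 ± 0.222 to 5.12 ± 1.68 CPM) and the B cell gene Cd22 (1.68, SE 0.20). All 18 cell cycle genes rose, with Aurkb at 2.68 (SE 0.22) and Cdk1 at 2.56 (SE 0.23). None fell in these lists, and the same counts passed when adjusted over the list alone. The medians were 2.71 for macrophage, 2.10 for interferon-stimulated, 1.94 for lymphocyte and 1.72 for cell cycle genes, with camera adjusted p of 3.79e-15, 1.62e-07, 0.00276 and 2.23e-08. The adjusted p were 0.131, 0.434, 0.434 and 0.35 with an estimated correlation.

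Other cell type markers in BAT moved in other ways. Endothelial genes fell in 7 of 10 and rose in none (7 lower adjusted over the list alone), with the VEGF receptor gene Kdr at -0.41 (SE 0.08), a median of -0.26 and a camera adjusted p of 0.279. Extracellular matrix genes rose in 15 of 22, such as Thbs1 (1.51), and Lox fell (-0.79; adjusted p = 0.13; 15 and 1 adjusted over the list alone). White adipocyte genes split 4 and 2 of 11 (adjusted p = 0.305; 4 and 2 adjusted over the list alone). Npr3, a natriuretic peptide receptor, went from 136 ± 34.0 to 573 ± 89.0 CPM and Adipoq from 676 ± 94.3 to 272 ± 118 CPM. Of the genes of proposed UCP1-independent heat cycles 5 rose and 5 fell of 21, over all genes and adjusted over the list alone (adjusted p = 0.771), with the calcium pump gene Atp2a3 at 2.47 (SE 0.12) and Gpd2, of the glycerol phosphate shuttle, at -1.13 (SE 0.09). Clock genes fell in 8 of 15 and rose in 1 (Hlf -0.82, Cry1 0.65; adjusted p = 0.191; 1 and 8 adjusted over the list alone). Of the immediate early genes 2 of 11 rose, such as Egr2 (2.04; adjusted p = 0.382; 2 adjusted over the list alone). The FGF receptor signalling list split 5 and 3 of 11 (adjusted p = 0.742; 5 and 3 adjusted over the list alone), with the feedback inhibitor gene Spred1 at 0.53 and the receptor gene Fgfr1 at -0.59. The widest falls included the neurotrophin receptor gene Ntrk3 (208 ± 33.7 to 3.08 ± 1.68 CPM), Pnldc1 (37.2 ± 4.31 to 1.94 ± 0.53 CPM) and Rspo4 (10.8 ± 4.67 to 0.152 ± 0.0766 CPM), and Akr1b7 went from 0.0301 ± 0.0211 to 18.3 ± 7.98 CPM.

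In BAT 9634 of 16032 tested genes passed an adjusted p of 0.05 for UCP1 KO against WT (60.1%), 4836 higher and 4798 lower, and 2865 of them changed over 2-fold. DESeq2 called 10045. Skeletal muscle RNA was present in part of the BAT libraries and may affect the lists above. The mean log2 CPM of 14 fibre genes ran from 1.65 to 10.4 and was highest in WT replicate 5. The list had a median of -1.46 for UCP1 KO against WT and did not pass the test (0 called over all genes and adjusted over the list alone, adjusted p = 0.581). Of the epithelial list 2 genes were measured, too few to test as a list, and the tight junction gene Cldn3 rose from 0.064 ± 0.0307 to 1.15 ± 0.561 CPM. None of the 3 blood genes in the list was called.

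In iWAT, loss of UCP1 went with higher genes of mitochondria and fuel oxidation. Of 51 respiratory chain and ATP synthase genes 48 rose and 1, Atp5g1 (-1.02), fell. Cycs, cytochrome c, went from 184 ± 50.5 to 676 ± 112 CPM (n = 6 each; log2 fold change 1.88, SE 0.19, adjusted p = 1.53e-07) and Uqcrc2 from 502 ± 116 to 1558 ± 181 CPM. Of 17 citric acid cycle genes 16 rose, with Suclg1 at 2.32 (SE 0.22) and Idh3a at 2.08 (SE 0.19). Of 20 fatty acid oxidation genes 19 rose, with the carnitine carrier gene Slc25a20 at 2.20 (SE 0.22) and Hadha at 2.08 (SE 0.20). Of 22 glucose uptake and glycolysis genes 16 rose, with Hk1 at 1.68 (SE 0.14) and Pgam1 at 1.98 (SE 0.17). Of 23 brown and beige adipocyte genes 17 rose and 2 fell. The glycerol kinase gene Gk went from 41.5 ± 17.6 to 466 ± 93.3 CPM (3.49, SE 0.33) and the potassium channel gene Kcnk3 rose by 2.48 (SE 0.23). Adrb3, the main adrenergic receptor of fat cells, and Lhx8 fell (-0.84 and -1.01).

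The median log2 fold changes in iWAT were 1.20 for the respiratory chain, 1.49 for the citric acid cycle and for glycolysis, 1.56 for fatty acid oxidation and 2.26 for brown and beige genes. Camera gave adjusted p of 1.71e-28, 4.75e-22 and 2.89e-11, 6e-20 and 1.64e-12 for these lists, and the adjusted p with an estimated correlation were 0.204 for the respiratory chain and 0.085 for the other lists. Adjusted over the list alone, 49 rose and 2 fell in the respiratory chain, 17 and 0 in the citric acid cycle, 19 and 0 in fatty acid oxidation, 16 and 0 in glycolysis, and 17 and 3 among brown and beige genes. Lipogenesis genes rose in 11 of 18 (none fell; 11 adjusted over the list alone; median 0.73, adjusted p = 0.000427), with the elongase gene Elovl6 at 2.14 and Acacb at 1.40. Cholesterol synthesis genes rose in 7 of 17, such as Cyp51 (1.30), with 6 adjusted over the list alone (median 0.54, adjusted p = 0.0333). Heat shock genes rose in 8 of 13 over all genes and adjusted over the list alone, such as the mitochondrial chaperone gene Hspd1 (1.26; median 0.67, adjusted p = 0.00151). With an estimated correlation the adjusted p were 0.639 for lipogenesis, 0.703 for cholesterol synthesis and 0.463 for heat shock genes.

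The ATF4 list was again past the threshold in iWAT, with 14 of 24 members higher and 2 lower (15 and 2 adjusted over the list alone; median 0.79, camera adjusted p = 4.12e-08), and this call held with an estimated correlation (adjusted p = 0.0145). Trib3, a pseudokinase induced by ATF4, went from 6.71 ± 2.38 to 61.4 ± 10.9 CPM (n = 6 each; log2 fold change 3.19, SE 0.21, adjusted p = 2.11e-09) and Ddit3 from 13.8 ± 1.78 to 54.5 ± 8.69 CPM. Phgdh, the first enzyme of serine synthesis, fell by 1.73 (SE 0.21) and Nupr1 fell by 0.76 (SE 0.21). The list of proposed heat cycles had 7 higher and 3 lower of 21 over all genes and adjusted over the list alone. Its median was -0.19 although its mean (0.14) and its test pointed up (adjusted p = 0.0282, and adjusted p = 0.463 with an estimated correlation). Gpd2 (1.77, SE 0.18) and Alpl (2.17, SE 0.23) rose, while Gamt and Gatm, which make creatine, fell (-1.23 and -0.90). Several members of that list, such as Ckm and Atp2a1, are abundant in skeletal muscle.

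Structural and white adipocyte genes were lower in iWAT with UCP1 loss. Extracellular matrix genes fell in 12 of 22, with Fbn1 at -1.19 (SE 0.23) and Dcn at -1.06 (SE 0.21), and 1, Postn, rose (0.80); the median was -0.71 (1 higher and 13 lower adjusted over the list alone). Of 13 white adipocyte genes 6 fell and 2 rose (7 and 2 adjusted over the list alone; median -0.70). Cfd, the secreted protease adipsin, went from 8014 ± 3000 to 1696 ± 864 CPM and Nnat fell by 2.61 (SE 0.43). Camera gave adjusted p = 0.00758 and 0.0403 for these lists, and adjusted p = 0.703 with an estimated correlation for both. Macrophage genes fell in 10 of 21, such as Csf1r (-0.84), and rose in 2, such as Lgals3 (1.03), over all genes and adjusted over the list alone (median -0.65, adjusted p = 0.0682). Interferon-stimulated genes split 3 and 3 of 16 over all genes and adjusted over the list alone (Rsad2 1.73, Gbp2 -0.44; median -0.10, mean 0.13, adjusted p = 0.854). Endoplasmic reticulum chaperone genes split 4 and 4 of 16 (Herpud1 0.71, Pdia4 -0.74; adjusted p = 0.854; 4 and 5 adjusted over the list alone). None of the 10 endothelial and none of the 18 cell cycle genes passed the test, over all genes or adjusted over the list alone (adjusted p = 0.854 each). Lipid droplet genes split into 3 higher, such as Plin2 (2.28), and 1 lower, Plin4 (-1.49), of 15 over all genes and adjusted over the list alone (adjusted p = 0.133). Clock genes had 4 higher, such as Cry1 (1.44), and 3 lower, such as Npas2 (-0.94), of 15 (adjusted p = 0.72; 4 and 4 adjusted over the list alone). Immediate early genes had 1 higher, Dusp1 (1.20), and 2 lower, such as Egr1 (-1.18), of 12 (adjusted p = 0.724; 1 and 1 adjusted over the list alone). The FGF receptor signalling list had 4 higher, such as Dusp6 (1.32, SE 0.17), and 2 lower, such as Fgfr2 (-0.92), of 12 over all genes and adjusted over the list alone (adjusted p = 0.504).

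In all, 7759 of 16751 iWAT genes were called (46.3%), 3736 higher and 4023 lower, and DESeq2 called 8201. The widest changes by the naming rule included Bmp8b, a secreted signal of the BMP family (0.229 ± 0.226 to 17.4 ± 7.09 CPM), Sptlc3 (0.1 ± 0.0936 to 20.3 ± 13.4 CPM) and Epn3 (0.0449 ± 0.00908 to 9.46 ± 3.34 CPM), and Podn fell by 2.89 (SE 0.32). The median log2 fold change of all iWAT genes was -0.13. Lymphocyte genes marked 12 of the 23 iWAT dissections, with a mean log2 CPM over 2 in WT replicates 1 to 4, UCP1 KO replicates 2, 4 and 5, dKO replicates 3, 4 and 5, and FGF21 KO replicates 1 and 4, up to 6.55. Neither the lymphocyte list (16 genes, median -1.54, adjusted p = 0.246) nor the skeletal muscle list (14 genes, median -0.52, adjusted p = 0.679) had a called member for UCP1 KO against WT, over all genes or adjusted over the list alone. Of 4 epithelial genes 1, Cdh1, fell (-1.38), and none of 3 blood genes was called.

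**Figure D2:**
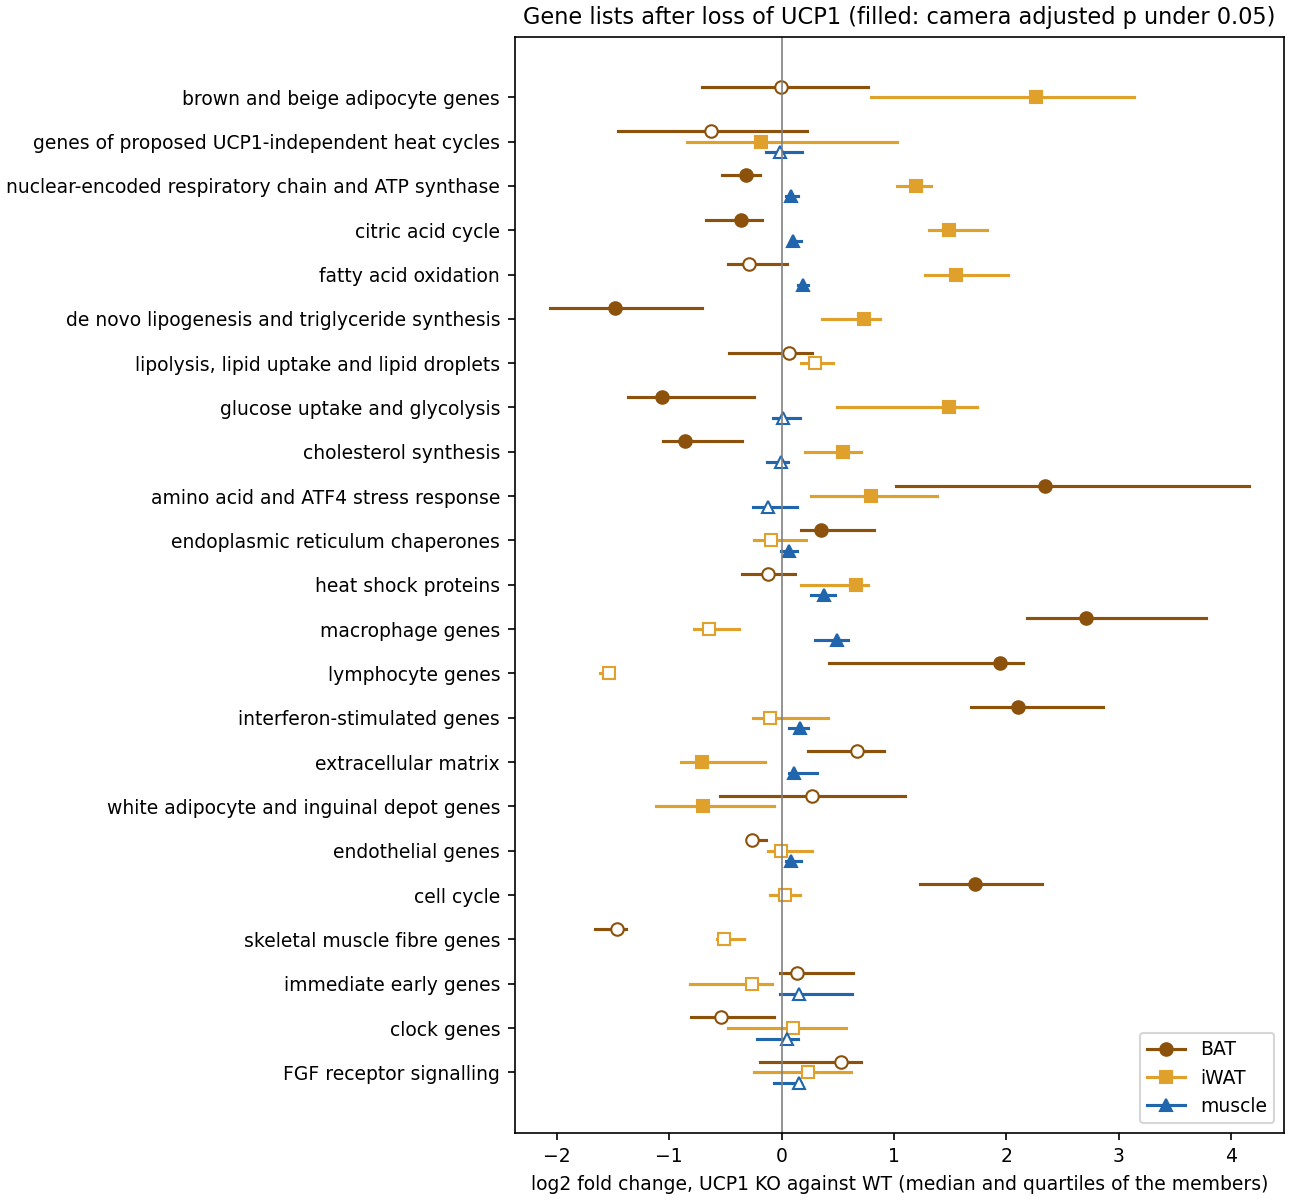
Median log2 fold change (UCP1 KO against WT) of each gene list in BAT, iWAT and muscle, with bars over the middle 50% of its members. Respiratory chain, citric acid cycle and lipogenesis genes lie below 0 in BAT (medians of -0.31, -0.37 and -1.48) and above 0 in iWAT (1.20, 1.49 and 0.73).

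Some genes of oxidative metabolism and protein folding rose in muscle. Of 20 fatty acid oxidation genes 13 rose, such as Acadl (246 ± 25.4 to 304 ± 20.3 CPM, n = 6 each; log2 fold change 0.31, SE 0.05, adjusted p = 0.000721). Of 51 respiratory chain genes 16 rose, such as Uqcrc2 (0.21, SE 0.04), and of 17 citric acid cycle genes 7 rose, such as Pdha1 (0.31, SE 0.04). Of 13 heat shock genes 8 rose, with Hsp90aa1 at 0.47 (SE 0.08) and Hsph1 at 0.44 (SE 0.08). None fell in these lists, and adjusted over the list alone 15, 22, 9 and 12 rose. The medians were 0.19, 0.09, 0.10 and 0.38, with camera adjusted p of 7.49e-10, 3.35e-08, 2.25e-07 and 7.49e-10. The heat shock call held with an estimated correlation (adjusted p = 0.0143), whereas the adjusted p with an estimated correlation were 0.38, 0.495 and 0.487 for the other lists.

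Among single muscle genes Mybph, a myosin-binding protein gene, went from 56.5 ± 10.2 to 260 ± 107 CPM (n = 6 each; log2 fold change 2.20, SE 0.22, adjusted p = 8.47e-06). Actc1, the cardiac actin gene that is also used in developing muscle, rose by 1.46 (SE 0.28), and Myog, a transcription factor of muscle differentiation, by 0.96 (SE 0.18). Cd27 (-1.60, SE 0.24) and Mettl21c (-1.05, SE 0.29) fell. Muscle atrophy and proteolysis genes rose in 4 of 18 and fast fibre genes fell in 3 of 11, such as Tnnt3 (-0.17), while Myh1 rose (0.32); 5 atrophy genes rose, and 1 fast fibre gene rose and 5 fell, adjusted over the list alone. Macrophage genes rose in 5 of 20 (11 adjusted over the list alone; median 0.50), such as Mrc1 (0.52, SE 0.15). Fat cell genes, which mark adipose tissue in the dissections, rose in 3 of 10 over all genes and adjusted over the list alone (median 0.46), such as Scd1 (1.03, SE 0.26). Camera gave adjusted p of 0.00581, 0.0283, 5.41e-07 and 0.00119 for the atrophy, fast fibre, macrophage and fat cell lists, and adjusted p of 0.495, 0.495, 0.492 and 0.492 with an estimated correlation.

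Endoplasmic reticulum chaperone genes (2 of 16 higher), endothelial genes (2 of 10), extracellular matrix genes (1 of 22, none adjusted over the list alone) and interferon-stimulated genes (1 of 16) also passed camera in muscle. Their adjusted p were 0.039, 0.0354, 0.039 and 0.0441, and 0.495, 0.492, 0.623 and 0.522 with an estimated correlation. The ATF4 list had 4 lower of 22, such as Vldlr (-0.31; adjusted p = 0.06; 2 higher and 5 lower adjusted over the list alone). Slow fibre genes had 1 of 11 higher, Mb, myoglobin (0.48, SE 0.09; 2 higher adjusted over the list alone; adjusted p = 0.593). The heat cycle list had 4 higher, such as the mitochondrial creatine kinase gene Ckmt2 (0.47), and 1 lower of 21 (adjusted p = 0.642; 4 and 3 adjusted over the list alone; median -0.01, mean 0.18). Glycolysis (2 higher, 1 lower of 22; adjusted p = 0.469), cholesterol synthesis (1 and 1 of 17; 0.593), immediate early (2 of 12 higher; 0.129), clock (2 of 15 lower, such as Nr1d1 at -0.55; 0.185) and FGF receptor signalling genes (1 of 12 lower, Fgfr4 at -0.33; 0.471) did not pass, with the same counts adjusted over the list alone, and none of 3 blood genes was called. Nnt, an inner mitochondrial membrane enzyme gene that differs between C57BL/6 strains, stood at 42.7 ± 6.05 CPM in WT and 109 ± 64.3 in UCP1 KO (1.35, SE 0.37, adjusted p = 0.0235). Single muscle libraries ran from 36.2 to 51.7 CPM in WT, 50.4 to 211 in UCP1 KO, 39.2 to 112 in FGF21 KO and 40.5 to 123 in dKO. This spread of Nnt points to a mixed strain background in the knockouts, away from the targeted genes. Values for loss of UCP1 or FGF21 may include it. In muscle 1860 of 15120 genes were called (12.3%), 890 higher and 970 lower, and 98 of them changed over 2-fold; DESeq2 called 2145. The count was 931, and fewer lists passed, with the fat cell list as a covariate, added after seeing the data. It was 921 with UCP1 KO and WT libraries alone.

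The hypothalamus changed little. Of 18020 genes 10 were called for UCP1 KO against WT by edgeR (979 at an unadjusted p under 0.05; 15 by DESeq2), 3 higher and 7 lower, and most of them lay beside Ucp1. Scoc went from 157 ± 13.5 to 102 ± 2.12 CPM (n = 6 each; log2 fold change -0.62, SE 0.04, adjusted p = 1.32e-09) and lies on chromosome 8 from 83434492 to 83458436. Mri1, which acts in methionine salvage, fell from 13.9 to 6.95 CPM (SE of the log2 fold change 0.08), Wdr83os fell by 0.49 (SE 0.06), Hook2 fell by 0.26 (SE 0.04) and Dcaf15 rose by 0.35 (SE 0.06). Away from that region Trh, the gene of thyrotropin-releasing hormone, rose from 51.8 ± 5.44 to 72.2 ± 8.20 CPM (0.48, SE 0.09, adjusted p = 0.0343). AK163592, which has no position here and so cannot be placed inside or outside that region, rose by 0.71 (SE 0.13). Il15 (-1.06), Mir709 (-2.73) and BC049805 (-0.35) completed the 10 and were named after their values were seen.

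Of the hypothalamic neuropeptide and receptor list 1 of 24 genes, Trh, was called (6 higher adjusted over the list alone; median 0.15, camera adjusted p = 8.18e-06, and adjusted p = 0.323 with an estimated correlation). Immediate early genes (median 0.27, adjusted p = 0.00281), microglia genes (0.10, adjusted p = 0.0104), respiratory chain genes (0.03, adjusted p = 0.00281) and endoplasmic reticulum chaperone genes (-0.04, adjusted p = 0.0104) passed camera with 0 called members over all genes. Of them 1 immediate early gene and none of the others was higher adjusted over the list alone. With an estimated correlation their adjusted p were 0.534, 0.534, 0.692 and 0.534. The ATF4 list lay at the threshold (median 0.04, adjusted p = 0.05, and adjusted p = 0.534 with an estimated correlation). Myelin (adjusted p = 0.899), astrocyte (0.116), cholesterol synthesis (0.246), heat shock (0.376), interferon-stimulated (0.551), clock (0.0976) and FGF receptor signalling genes (0.376) had no called member over all genes and did not pass. Adjusted over the list alone, 1 astrocyte gene was lower and clock genes had 1 higher and 1 lower. Markers of neighbouring regions were present in single dissections. Choroid plexus genes had a mean log2 CPM over 3 in WT replicates 1 and 4, UCP1 KO replicates 2 and 3, dKO replicate 1 and FGF21 KO replicate 4. For UCP1 KO against WT the choroid plexus (median -0.46, adjusted p = 0.376), pituitary (0.41, 0.374), cortical (-0.07 with a mean of 0.04, 0.376), striatal (0.04, 0.249) and thalamic lists (-0.05, 0.321) did not pass and had no called member. Without the 6 libraries with choroid plexus genes, left out after seeing the data, 6 genes were called for UCP1 KO and none for FGF21 KO.

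Genes close to Ucp1 were called more often than genes elsewhere in hypothalamus and muscle. In hypothalamus 7 of the 8 called genes with a position lay within 10 Mb of Ucp1, so that 7 of 137 tested genes in the window were called against 1 of 16284 elsewhere (two-sided Fisher's exact test, p = 1.92e-14). In dKO against FGF21 KO, which shares no library with that comparison, 8 of 137 were called near Ucp1 against 1 elsewhere (Fisher's exact test, p = 1.71e-16). In muscle 27.3% of the genes near Ucp1 were called for UCP1 KO against 12.4% elsewhere (Fisher's exact p = 1.12e-05), in BAT 70.5% against 61.1% (p = 0.0397; 62.1% and p = 0.762 with a 20 Mb window), and in iWAT 47.5% in both (p = 1). Around Fgf21 the calls were few and differed between tissues. For FGF21 KO against WT, Rasip1, which lies on chromosome 7 from 45627537 to 45639092, was the 1 gene called in hypothalamus (-0.81, SE 0.12, adjusted p = 0.0126; Fisher's exact p = 0.00968). It was 1 of 3 in muscle with its neighbour Mamstr (-0.58, SE 0.09, and -0.78, SE 0.13; Fisher's exact test, p = 0.000311), and 1 of 145 genes near Fgf21 was called in BAT (p = 0.0288) and 0 of 154 in iWAT. For dKO against UCP1 KO 2 of 159 were called in hypothalamus (Fisher's exact p = 9.32e-05), 5 of 145 in BAT (p = 0.117), 0 of 154 in iWAT and 0 of 146 in muscle. The calls in hypothalamus and muscle for loss of FGF21 fell to 0 without single libraries, which are named with each comparison below. Wdr83os was lower with UCP1 loss in all 4 tissues (-0.46 in BAT, -0.36 in iWAT, -0.46 in muscle and -0.49 in hypothalamus), the 1 gene called in the same direction in every tissue.

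**Figure D3:**
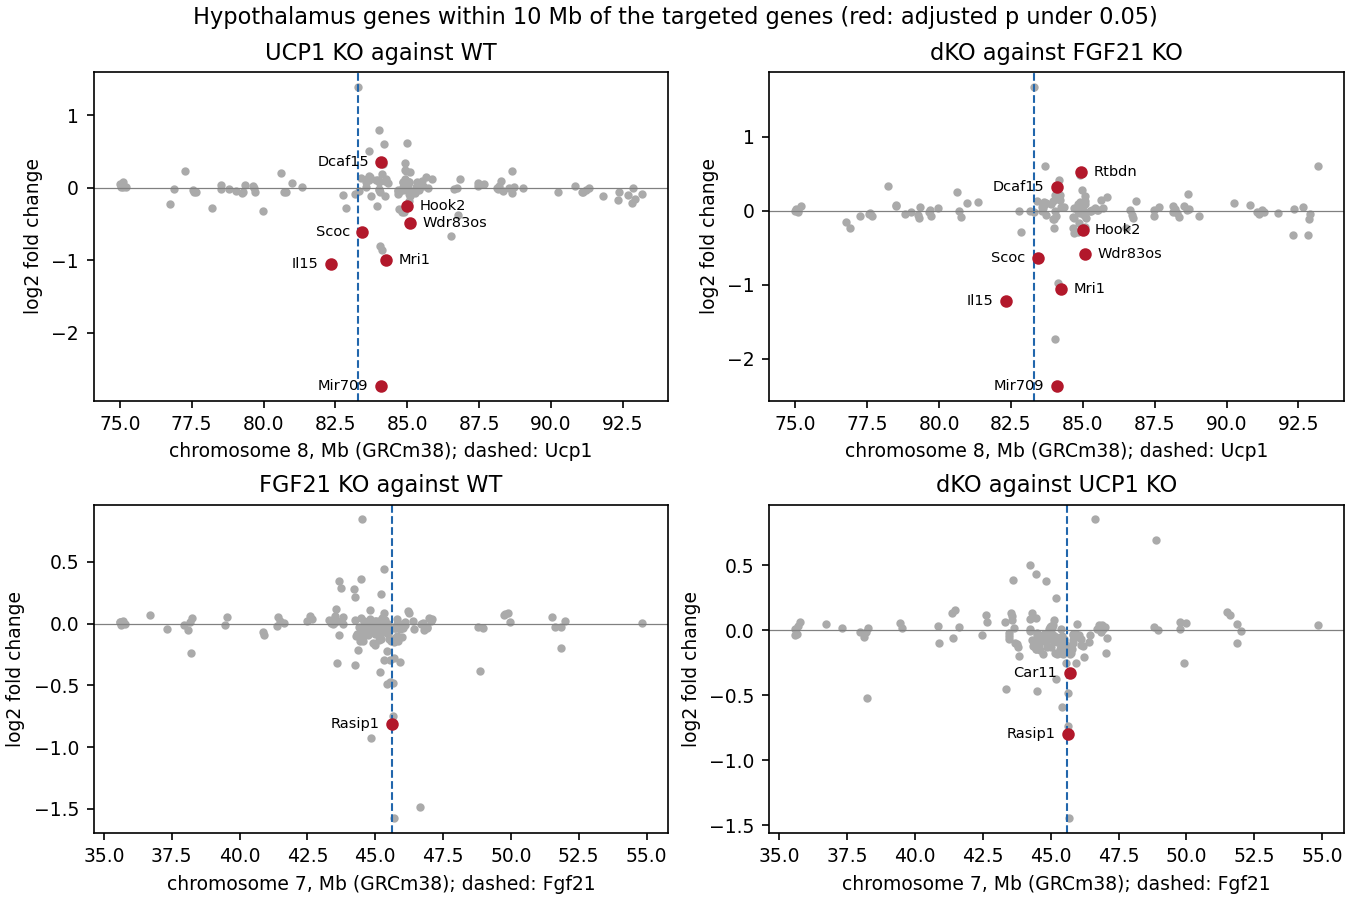
Log2 fold changes of hypothalamus genes within 10 Mb of Ucp1 (UCP1 KO against WT; dKO against FGF21 KO) and of Fgf21 (FGF21 KO against WT; dKO against UCP1 KO), against position (GRCm38), with called genes in red. The calls near Ucp1 for UCP1 KO against WT span 2.75 Mb, with Scoc at -0.62 and Wdr83os at -0.49.

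Loss of FGF21 alone changed few genes. In BAT 4 of 16032 were called by edgeR (1514 at an unadjusted p under 0.05; 34 by DESeq2). Adcy3, an adenylate cyclase gene, rose from 365 ± 39.9 to 562 ± 18.6 CPM (n = 5 each; log2 fold change 0.62, SE 0.11, adjusted p = 0.0432). Mob1b rose from 15.3 ± 1.80 to 24.4 ± 2.26 CPM (0.67, SE 0.12, adjusted p = 0.0432). The other two, chosen after their values were seen, were AK049852 (-2.03, SE 0.27) and Fut1. The latter lies beside Fgf21 on chromosome 7 from 45617606 to 45621059 and stood at 0.00517 CPM in WT and 0.302 ± 0.132 in FGF21 KO. It stood at 0.426 ± 0.148 CPM in UCP1 KO and 0.368 ± 0.209 in dKO (n = 6 each), so WT was the group apart. In iWAT the 1 gene called was Fgf21 itself (456 at an unadjusted p under 0.05; 1 by DESeq2). In muscle 3 were called (635; 3 by DESeq2), Rasip1, Mamstr and the T cell gene Cd28 (0.54, SE 0.10, adjusted p = 0.0464), and in hypothalamus 1, Rasip1 (446; 18 by DESeq2). The BAT count was 1 without WT replicate 2 or 3, 7 without WT replicate 1 or UCP1 KO replicate 2, and 14 without FGF21 KO replicate 1. It was 2 without UCP1 KO replicate 3, 4 or 6, dKO replicate 2, 3, 4 or 5, or FGF21 KO replicate 2, 3 or 5. The iWAT count was 2 without FGF21 KO replicate 3. The muscle count was 0 without WT replicate 2 or FGF21 KO replicate 5 and 1 without WT replicate 1, 3 or 4, UCP1 KO replicate 4, dKO replicate 3 or 6, or FGF21 KO replicate 4. The hypothalamus count was 0 without WT replicate 1, 3 or 4 or FGF21 KO replicate 1, 2 or 3, 2 without WT replicate 6 or dKO replicate 3, 3 without dKO replicate 2 or FGF21 KO replicate 5, and 16 without dKO replicate 5.

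For FGF21 KO against WT 4, 7, 6 and 4 lists passed camera in BAT, iWAT, muscle and hypothalamus, and none held with an estimated correlation. In BAT cell cycle genes (median 0.34, camera adjusted p = 4.59e-06), brown and beige genes (0.05, 0.00135; 3 higher adjusted over the list alone), immediate early genes (-0.34, 0.0276) and clock genes (-0.22, 0.0276; 1 higher and 2 lower adjusted over the list alone) passed with 0 members called over all genes. Their adjusted p with an estimated correlation were 0.67, 0.647, 0.959 and 0.647. Skeletal muscle fibre genes had a median of -0.91 in BAT (adjusted p = 0.1, 0 called over all genes and adjusted over the list alone). In hypothalamus interferon-stimulated genes had a median of 0.42 (camera adjusted p = 1.76e-09, and adjusted p = 0.302 with an estimated correlation), beside lower choroid plexus (-0.93, adjusted p = 0.0468) and pituitary markers (-0.49, adjusted p = 0.00322; adjusted p = 0.816 and 0.302 with an estimated correlation) and endoplasmic reticulum chaperones (-0.04, adjusted p = 3.39e-05, and adjusted p = 0.302 with an estimated correlation). In iWAT 7 lists passed, among them interferon-stimulated genes (0.30, adjusted p = 9.82e-06) and white adipocyte genes (-0.10, adjusted p = 3.11e-06; 1 lower adjusted over the list alone), together with skeletal muscle fibre genes (2.51, adjusted p = 0.0195), whose mean log2 CPM was 8.36 and 5.68 in FGF21 KO replicates 3 and 5 and 4.17 and 6.9 in WT replicates 3 and 4. With an estimated correlation the adjusted p was 0.978 for each of these 3 lists. In muscle 6 lists passed, among them the respiratory chain (-0.04, adjusted p = 1.36e-05) and extracellular matrix (0.16, adjusted p = 0.000344). Fat cell markers (0.25, adjusted p = 0.0231) and macrophage genes (0.165, adjusted p = 0.00688) were higher beside them, and the adjusted p was 0.728 for these 4 lists with an estimated correlation.

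With both genes lost, most of the fuel-handling genes of BAT were again lower than in WT. Lipogenesis genes fell in 17 of 18 and rose in 1 (median -1.47), glycolysis genes fell in 13 of 22 and rose in 2 (-1.15) and respiratory chain genes fell in 30 of 51 and rose in 2 (-0.26), with Mlxipl at -2.29 (SE 0.13) and Hk2 at -2.00 (SE 0.12). ATF4 genes rose in 21 of 24 and 1, Nupr1, fell (median 2.12, camera adjusted p = 6.18e-29, and 1.89e-06 with an estimated correlation); Slc7a5 reached 28.8 ± 1.38 CPM (n = 6) and Cth, of cysteine synthesis, rose by 3.83 (SE 0.17). Macrophage genes rose in 19 of 21 (2.20), all 16 interferon-stimulated genes rose (2.61), and 17 of 18 cell cycle genes rose (1.54). Camera gave adjusted p = 8.85e-08, 4.26e-08, 0.000369, 8.5e-11, 4.81e-10 and 3.67e-07 for lipogenesis, glycolysis, respiratory chain, macrophage, interferon-stimulated and cell cycle genes. With an estimated correlation these were 0.382, 0.121, 0.779, 0.31, 0.382 and 0.382. Adjusted over the list alone the counts were the same, except that 31 respiratory chain genes fell. Skeletal muscle fibre genes had a median of -2.12 beside them (adjusted p = 0.376, 0 called over all genes and adjusted over the list alone). In total 9469 BAT genes were called, 4768 higher and 4701 lower (9828 by DESeq2).

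In dKO iWAT, respiratory chain genes rose in 48 of 51 and fell in 1 (median 1.12), fatty acid oxidation genes in 19 of 20 (1.54), citric acid cycle genes in 16 of 17 (1.37) and brown and beige genes in 17 of 23 (2.39), with 1 lower, Lhx8. Ehhadh, of peroxisomal fatty acid oxidation, went from 139 ± 58.0 in WT to 1061 ± 399 CPM (n = 6 each; log2 fold change 2.93, SE 0.29). Camera gave adjusted p of 4.81e-30, 4.76e-22, 4.01e-23 and 1.27e-15, and 0.184 for the respiratory chain and 0.0684 for the other lists with an estimated correlation; the counts adjusted over the list alone were the same. The ATF4 list (14 higher and 2 lower of 24; 15 and 2 adjusted over the list alone; median 0.65, adjusted p = 1.3e-08) held with an estimated correlation (adjusted p = 0.00955). Markers of other tissue were lower beside these lists, skeletal muscle fibre genes by a median of -4.05 (adjusted p = 0.413) and lymphocyte genes by -0.905 (adjusted p = 0.366), with 0 members called over all genes and adjusted over the list alone. In total 6192 iWAT genes were called, 3181 higher and 3011 lower (6550 by DESeq2). In dKO muscle 1558 were called, 733 higher and 825 lower (1847 by DESeq2; 526 with the fat cell list as a covariate, added after seeing the data). There 11 of 20 fatty acid oxidation genes rose (18 adjusted over the list alone), such as Cpt2 (0.41, SE 0.07). So did 11 of 20 macrophage genes (12 adjusted over the list alone), 8 of 16 interferon-stimulated genes (14 adjusted over the list alone), such as Oas2 (0.70, SE 0.14), and 3 of 10 fat cell markers (6 adjusted over the list alone). Rbm3, a cold-inducible RNA-binding protein gene, went from 92.3 ± 9.95 to 46.3 ± 8.67 CPM (SE of the log2 fold change 0.11). In muscle 12 lists passed camera, these 4 among them with adjusted p of 1.17e-11, 5.5e-10, 5.5e-10 and 3.59e-05, and 0.233, 0.28, 0.223 and 0.293 with an estimated correlation.

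In dKO hypothalamus 10 genes were called against WT by edgeR (502 at an unadjusted p under 0.05; 22 by DESeq2), with Scoc (-0.57), Mri1 (-0.98) and Rasip1 (-0.72) among them. The count was 5 without dKO replicate 1 and 6 without the 6 libraries with choroid plexus genes. Of 6 lists that passed camera, astrocyte genes were the 1 that held with an estimated correlation (adjusted p = 0.0241; median -0.11, camera adjusted p = 0.00251), with 0 of 9 members called and 1 lower adjusted over the list alone. The others were interferon-stimulated genes, which were higher (0.15, camera adjusted p = 0.0171), and myelin (-0.07, 0.0171), microglia (-0.06, 0.0359), respiratory chain (-0.01, 0.0359) and heat shock genes (-0.02, 0.0493). Choroid plexus (-0.61, 0.11) and cortical markers (-0.27, 0.106) were lower without passing. No member of these 7 lists was called, over all genes or adjusted over the list alone. Scoc, Wdr83os, Rasip1 and AK049852 were lower than WT in dKO in all 4 tissues.

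The comparison of dKO with UCP1 KO asks what FGF21 contributes when UCP1 is missing and Fgf21 RNA is high. In BAT the FGF receptor signalling list was lower: 3 of 11 members fell and Fgfr2 rose (5 and 2 adjusted over the list alone), with a median of -0.34, a camera adjusted p of 9.55e-05 and an adjusted p of 0.00687 with an estimated correlation. Etv5, an ETS factor induced by FGF signalling, went from 8.58 ± 1.56 in UCP1 KO to 4.02 ± 0.899 CPM in dKO (n = 6 each; log2 fold change -1.10, SE 0.19, adjusted p = 0.00543). The feedback inhibitor gene Spred1 went from 40.8 ± 2.04 to 27.9 ± 0.670 CPM (-0.55, SE 0.09). In iWAT the list had a median of -0.36 and 1 of 12 members called, Spred1 (42.0 ± 2.90 to 30.8 ± 2.83 CPM; -0.45, SE 0.08, adjusted p = 0.0263), with 5 lower adjusted over the list alone. Its camera adjusted p was 1.08e-07 and held with an estimated correlation (adjusted p = 0.000961). Dusp4, a MAP kinase phosphatase gene, fell in both depots, from 73.1 ± 17.1 to 24.8 ± 3.54 CPM in BAT and from 102 ± 7.05 to 39.6 ± 8.66 CPM in iWAT. In WT, Spred1 stood at 28.2 ± 5.73 CPM in BAT (n = 5) and 32.2 ± 2.09 in iWAT (n = 6), and Dusp4 at 43.1 ± 20.1 and 23.3 ± 4.02.

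**Figure D4:**
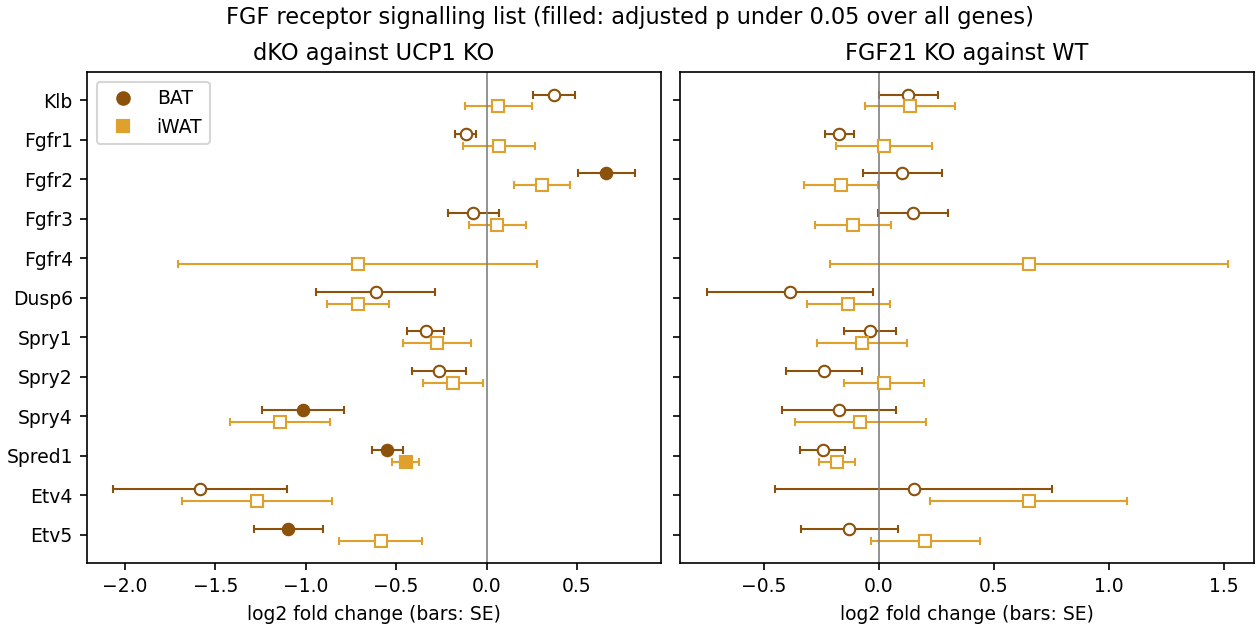
Log2 fold changes (bars are SE) of the FGF receptor signalling genes in BAT and iWAT for dKO against UCP1 KO and for FGF21 KO against WT. For dKO against UCP1 KO, Spred1 lies at -0.55 in BAT and -0.45 in iWAT, and Etv5 at -1.10 in BAT.

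Other BAT genes lower in dKO than in UCP1 KO included Lcn2, the secreted protein lipocalin 2, which stood at 0.478 ± 0.0977 CPM in WT (n = 5), 62.6 ± 19.2 in UCP1 KO and 18.2 ± 8.50 in dKO (n = 6 each; log2 fold change -1.79, SE 0.25, adjusted p = 0.00114). Loxl4, of matrix cross-linking, fell by 1.36 (SE 0.24) and Cpt1a fell by 0.66 (SE 0.09). Macrophage genes fell in 5 of 21 and rose in none (10 lower adjusted over the list alone; median -0.51, camera adjusted p = 1.11e-12, and adjusted p = 0.265 with an estimated correlation), with C1qc at -0.71 (SE 0.11) and C1qa at -0.64 (SE 0.11). Interferon-stimulated genes went the other way (median 0.37, camera adjusted p = 0.00069) and lymphocyte genes were lower (-0.31, adjusted p = 0.0181). Both had 0 members called, over all genes and adjusted over the list alone, and adjusted p = 0.681 with an estimated correlation. Respiratory chain genes had a median of 0.11 with 0 of 51 called (12 higher adjusted over the list alone; adjusted p = 4.99e-08). Fatty acid oxidation genes had 2 higher and 1 lower of 20 (12 and 1 adjusted over the list alone; 5.25e-06), and citric acid cycle genes 1 higher of 17, Suclg2 at 0.24 (6 adjusted over the list alone; 5.25e-06). Their adjusted p with an estimated correlation were 0.681, 0.666 and 0.662. Tbc1d16 (1.45, SE 0.32), Dusp15 (1.40, SE 0.29) and Rasef (1.13, SE 0.20) rose. In total 278 BAT genes were called, 123 higher and 155 lower (2669 at an unadjusted p under 0.05; 730 by DESeq2). The count was 50 without the 6 libraries with muscle genes at a mean log2 CPM over 7 and 418 with the muscle list as a covariate, both added after seeing the data. It was 144, 523, 99, 169 and 143 without UCP1 KO replicate 1, 2, 3, 5 and 6, and 151, 104, 115, 106 and 184 without dKO replicate 1, 2, 3, 5 and 6.

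In iWAT 6 genes were called for dKO against UCP1 KO, all lower (486 at an unadjusted p under 0.05; 14 by DESeq2). They were Fgf21, Hsd11b1, Dusp4, Spred1, Spred2 (-0.57, SE 0.10, adjusted p = 0.0396) and, named after its value was seen, Gpr3 (-2.50, SE 0.44). Hsd11b1, which activates glucocorticoids, fell (178 ± 34.2 to 60.6 ± 5.46 CPM, n = 6 each; log2 fold change -1.56, SE 0.20, adjusted p = 0.00139). The count was 3 without UCP1 KO replicate 1, 3, 4, 5 or 6, dKO replicate 1, 5 or 6, or FGF21 KO replicate 5. In iWAT 12 lists passed camera, with FGF receptor signalling the 1 that held with an estimated correlation. Among the others macrophage (median 0.30, camera adjusted p = 1.42e-05, and adjusted p = 0.567 with an estimated correlation) and respiratory chain genes (-0.09, 0.000458, and adjusted p = 0.732 with an estimated correlation) had 0 called members, over all genes and adjusted over the list alone. So did extracellular matrix (0.225, 0.000295), citric acid cycle (-0.14, 0.00104), glycolysis (-0.17, 0.00107), cell cycle (0.28, 0.00474), lipogenesis (-0.14, 0.00524), heat shock (-0.13, 0.00873), immediate early (0.23, 0.00921), clock (-0.15, 0.0151) and fatty acid oxidation genes (-0.07, 0.0324). The skeletal muscle list had a median of -3.57 in this comparison (adjusted p = 0.297, 0 called over all genes and adjusted over the list alone). In muscle 0 genes were called by edgeR (877 at an unadjusted p under 0.05; 2 by DESeq2). Muscle interferon-stimulated genes (median 0.28, camera adjusted p = 4.69e-12; 0 of 16 called, 5 higher adjusted over the list alone) and heat shock genes (-0.10, 1.75e-07; 0 of 13 called, 1 lower adjusted over the list alone) held with an estimated correlation (adjusted p = 0.0492 for both). Slow fibre genes (-0.42, 4.19e-08) had an adjusted p of 0.257 with an estimated correlation and no called member, over all genes or adjusted over the list alone. In hypothalamus Rasip1 (-0.80, SE 0.12, adjusted p = 0.0119) and Car11 (-0.33, SE 0.06, adjusted p = 0.0334), both within 10 Mb of Fgf21, were called (731 at an unadjusted p under 0.05; 7 by DESeq2). The count was 0 without UCP1 KO replicate 4 or dKO replicate 1, 2 or 5, and 1 without WT replicate 1, 3 or 4, UCP1 KO replicate 1, 3, 5 or 6, dKO replicate 4, or FGF21 KO replicate 1, 2 or 4. Among 7 hypothalamus lists that passed, microglia genes had a median of -0.15 (camera adjusted p = 1.2e-06, and adjusted p = 0.232 with an estimated correlation) beside lower cortical (-0.32, adjusted p = 0.0279) and pituitary markers (-0.80, adjusted p = 0.0432, 2 lower adjusted over the list alone; adjusted p = 0.489 and 0.471 with an estimated correlation).

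The direction of the UCP1 response was nearly always the same with and without FGF21. Of the genes called for UCP1 KO against WT, 9530 of 9634 in BAT (98.9%, 95% Clopper-Pearson interval 98.7 to 99.1), 7701 of 7759 in iWAT (99.3%, 99 to 99.4), 1802 of 1860 in muscle (96.9%, 96 to 97.6) and 10 of 10 in hypothalamus had the same sign in dKO against FGF21 KO, which shares no library with the first comparison. Genes are not independent, so the intervals cover counting error only. The median ratio of the second fold change to the first was 0.882 in BAT, 0.826 in iWAT, 0.76 in muscle and 1.02 in hypothalamus, and 8096, 5363, 772 and 8 genes were called in both with the same sign. Genes chosen in the first comparison carry its chance values, which by itself lowers such a ratio. The interaction of both knockouts gave 0 calls by edgeR in each tissue, with 1168, 429, 538 and 493 genes at an unadjusted p under 0.05 and 20, 0, 1 and 0 by DESeq2 in BAT, iWAT, muscle and hypothalamus. The BAT count was 1 without WT replicate 2, dKO replicate 1 or 6, or FGF21 KO replicate 1, 2 without UCP1 KO replicate 5 and 4 without WT replicate 4, and the hypothalamus count was 7 without dKO replicate 5. In simulated data the interaction recovered 58.2% of 2-fold and 84.8% of 4-fold changes in BAT, and 44.8% and 69.7% in iWAT. Real data may give other rates. For the interaction 8, 16, 3 and 7 lists passed in BAT, iWAT, muscle and hypothalamus, and none held with an estimated correlation. In iWAT the skeletal muscle list (median -6.13, adjusted p = 0.00835) and the lymphocyte list (0.78, adjusted p = 0.00654) were among them, with 0 called members over all genes and adjusted over the list alone. BAT macrophage genes (median -0.78; 0 of 21 called, 11 lower adjusted over the list alone; camera adjusted p = 1.05e-15) passed camera for the interaction, as did cell cycle genes (-0.59; 0 of 18, 4 lower adjusted over the list alone; 6.06e-12). Their adjusted p were 0.156 and 0.171 with an estimated correlation. FGF receptor signalling genes lay at -0.23 in BAT (adjusted p = 0.00439) and -0.24 in iWAT (adjusted p = 0.000683). They had adjusted p = 0.0793 and 0.054 with an estimated correlation and 1 lower member in each adjusted over the list alone.

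**Figure D5:**
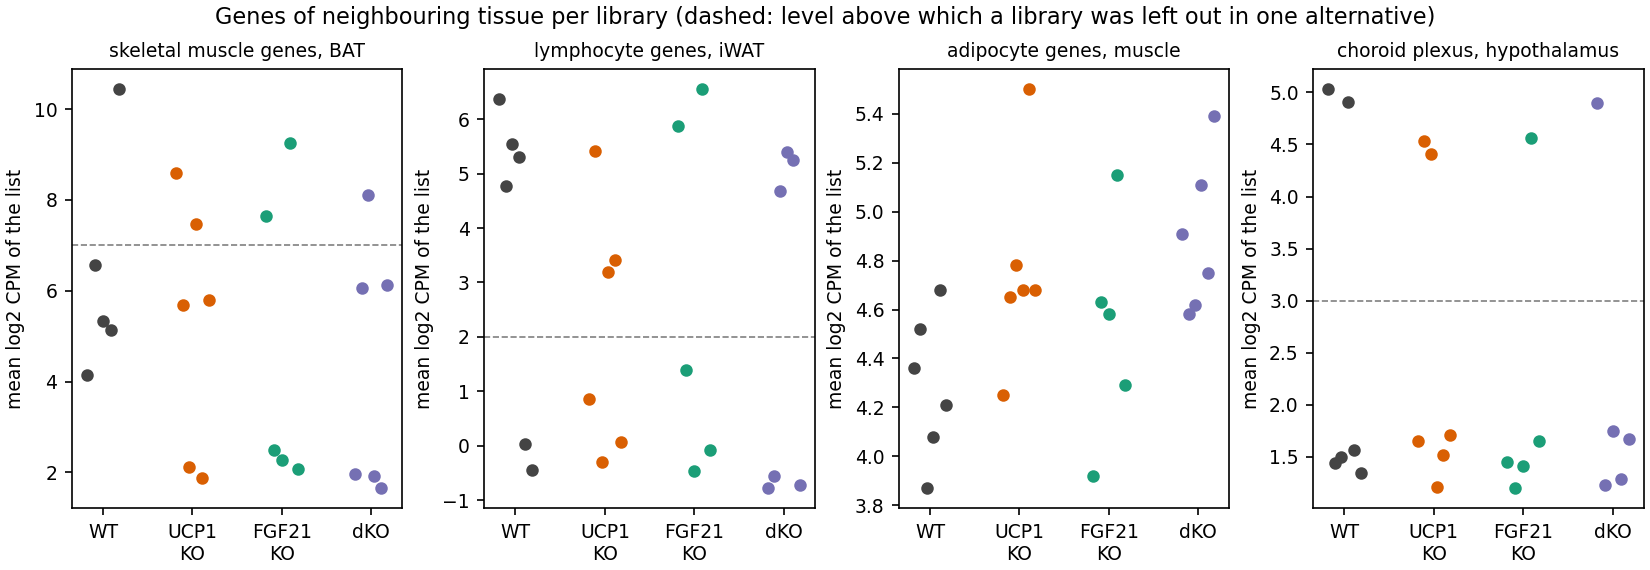
Mean log2 CPM of marker genes of other tissue in each library: skeletal muscle genes in BAT, lymphocyte genes in iWAT, fat cell genes in muscle and choroid plexus genes in hypothalamus. BAT WT replicate 5 reaches 10.4 for skeletal muscle genes and iWAT FGF21 KO replicate 4 reaches 6.55 for lymphocyte genes.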

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

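The tests of the difference between depots, the tests of the patterns weighed here and the splits for UCP1 KO against WT in BAT were chosen only after the result was seen; the other splits were planned.

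Dixon's test for a single far sample was run on 64 groups of libraries and picked out 10, where chance gives about 1 in 20, or 3.2. Fgf21 stood at 10.1 CPM in BAT UCP1 KO replicate 5, below the others of its group. Nnt stood at 34.4 CPM in BAT WT replicate 5, 22.5 in BAT UCP1 KO replicate 1 and 17.6 in BAT FGF21 KO replicate 4, each above its group, and at 23.6 CPM in hypothalamus FGF21 KO replicate 4, below its group. These 3 BAT libraries also had skeletal muscle genes at a mean log2 CPM over 7. Choroid plexus genes lay at a mean log2 CPM of 4.90 in hypothalamus dKO replicate 1 and 4.56 in FGF21 KO replicate 4, and skeletal muscle genes at 6.43 in iWAT UCP1 KO replicate 2, each above its group. Total counts were 69.9 M in hypothalamus dKO replicate 4 and 18.1 M in muscle dKO replicate 1 (1 M is 1e6 counts).

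UCP1 KO against WT differed between BAT and iWAT. For each of 23 lists the difference of mean log2 CPM between UCP1 KO and WT was compared between the depots by permuting genotype labels within each depot (426888 permutations, BH over lists). Of these 14 lists differed, 11 of them with opposite signs. The iWAT effect minus the BAT effect was 2.01 for brown and beige genes (0.12 in BAT, 2.13 in iWAT; adjusted p = 0.00478), 1.51 for the respiratory chain (-0.34, 1.17), 2.01 for the citric acid cycle (-0.44, 1.56) and 1.90 for glycolysis (-0.76, 1.14), with adjusted p = 1.79e-05 for these 3, whose p of 2.34e-06 is the smallest the permutations can give. It was 1.61 for fatty acid oxidation (-0.03, 1.59; adjusted p = 0.00232), 2.37 for lipogenesis (-1.57, 0.80; 0.000162), 1.32 for cholesterol synthesis (-0.83, 0.49; 0.000323) and 0.60 for heat shock genes (-0.07, 0.53; 0.00485). It was -0.48 for endoplasmic reticulum chaperones (0.45, -0.03; 0.0033), -3.20 for macrophage genes (2.85, -0.36; 0.000377), -2.01 for interferon-stimulated genes (2.10, 0.09; 0.00565), -1.07 for extracellular matrix (0.52, -0.56; 0.000802), -0.94 for white adipocyte genes (0.20, -0.73; 0.00635) and -1.61 for cell cycle genes (1.71, 0.10; 0.0218). The ATF4 list did not pass (2.49 in BAT, a difference of -1.49; adjusted p = 0.11). The test treats the depots as independent, although some libraries may come from the same mouse; for the respiratory chain the iWAT median was 1.049 without libraries with lymphocyte genes.

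Calls near the targeted genes: in hypothalamus they cluster around Ucp1 for UCP1 KO against WT (Fisher's exact p = 1.92e-14) and around Fgf21 for dKO against UCP1 KO (p = 9.32e-05). With few calls, none near the other targeted gene says little. The second p rests on 2 genes (0 without some single libraries or those with choroid plexus genes). Chance is argued against for Rasip1 (-0.80, and -0.81 for FGF21 KO against WT) and left open for Car11. DNA of the donor strain carried along with each knocked-out gene is a candidate explanation that these values fit, with this weaker support near Fgf21. An effect of the construct on its neighbours cannot be told apart from it, since the called genes near Ucp1 span 2.75 Mb and no sequence variants were examined.

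Genes called with UCP1 loss in BAT: a few abundant genes setting the library sizes would shift all log2 fold changes by 1 amount, but 9427 genes or more passed the threshold after any such shift from -3 to 3. Skeletal muscle in some dissections is argued against as the whole cause by the 9297 calls without the libraries over the cut of 7. The count also fell by no more than 1.5 times with muscle genes as a covariate. Lower levels of these genes remained without those libraries, at a mean log2 CPM of 4.14 to 6.56 in WT and 1.87 to 5.8 in UCP1 KO. A part played by muscle RNA is thus not excluded. A lower share of fat cells would raise markers of every other cell type. Macrophage genes rose in 19 of 21 and lymphocyte genes in 12 of 16, but endothelial genes fell in 7 of 10 (median -0.261). Endothelial genes may change apart from the share of fat cells, so this 1 list cannot decide. A lower share of fat cells stays open as a part of the cause. A response to the loss of UCP1, including a change in immune cells, stays open as a hypothesis found and tested on the same data, and so does a difference in strain background away from the targeted genes, which was not tested.

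Respiratory chain genes higher in iWAT with UCP1 loss: the median of the list was 1.198, 1.049 without the libraries with lymphocyte genes and 1.091 with lymphocyte and skeletal muscle genes as covariates. The median of 1.049 rests on WT replicates 5 and 6 and UCP1 KO replicates 1, 3 and 6 alone. These medians argue against lymph node or muscle in the dissections as the whole cause. A response of the depot to loss of UCP1 may remain, as a hypothesis from the same data; other causes, such as differences between litters or in strain background, were not tested.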

How the results depend on the processing

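The settings with a covariate for genes of other tissue and without libraries high in such genes were chosen after seeing the data. Counts per gene above counting error limit what can be called: in simulated data with 2-fold changes, 82.1% were recovered for UCP1 KO against WT in BAT, 64.2% in iWAT, 92.5% in muscle and 91% in hypothalamus, and 44.8% for the interaction in iWAT. For named genes, 460 values kept direction and side of the threshold with DESeq2 and 4 gained a call, 463 kept both with RLE size factors (1 lost its call), 448 with no low-count filter (17), 413 with the compared groups alone (33), 418 with the covariate (43), 302 without libraries with other tissue (42) and 10013 with a library left out (402). Reversed was Nnt for UCP1 KO against WT in BAT, from -0.06 to 0.98 without libraries with other tissue and to 1.45 without WT replicate 5; its lowest value with a library left out was -0.57, without UCP1 KO replicate 1. Except where construction is named below, the cause was not tested.

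With an estimated inter-gene correlation, lists past the threshold for UCP1 KO, FGF21 KO and dKO against WT, dKO against UCP1 KO and the interaction went from 11, 4, 11, 11 and 8 to 1, 0, 1, 1 and 0 in BAT, from 12, 7, 10, 12 and 16 to 1, 0, 1, 1 and 0 in iWAT, from 12, 6, 12, 5 and 3 to 1, 0, 0, 2 and 0 in muscle and from 6, 4, 6, 7 and 7 to 0, 0, 1, 0 and 0 in hypothalamus. With DESeq2, calls for FGF21 KO against WT were 34 in BAT and 18 in hypothalamus (edgeR 4 and 1), for dKO against WT 22 in hypothalamus (10), for dKO against UCP1 KO 730, 14, 2 and 7 in BAT, iWAT, muscle and hypothalamus (278, 6, 0 and 2) and for the interaction 20 in BAT and 1 in muscle (0 and 0). The share of genes with the same sign of UCP1 loss with and without FGF21 was 98.64% in BAT and 98.62% in iWAT with DESeq2 (98.92% and 99.25%), 98.53% and 98.93% with no low-count filter, and 98.97% in iWAT with RLE size factors. No low-count filter gave 1 interaction call in BAT and 3 calls for dKO against UCP1 KO in iWAT. Fits with the compared groups alone gave 921 calls for UCP1 KO against WT in muscle (1860) and 13 for FGF21 KO against WT in hypothalamus.

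With the covariate, BAT calls were 2 for FGF21 KO against WT and 418 for dKO against UCP1 KO; muscle calls were 931 for UCP1 KO, 1 for FGF21 KO and 526 for dKO against WT (1860, 3 and 1558), muscle lists for UCP1 KO 7 (12) and the muscle share of equal signs 99.25% (96.88%); hypothalamus lists for dKO against UCP1 KO were 4 (7). Without libraries with other tissue, BAT had 1 call and 9 lists for FGF21 KO, 50 calls for dKO against UCP1 KO and 100% equal signs of FGF21 loss (75%); iWAT had 0 calls and 11 lists for FGF21 KO and 98.98% equal signs of UCP1 loss; hypothalamus calls were 6, 0, 6 and 0 for UCP1 KO, FGF21 KO, dKO against WT and dKO against UCP1 KO (10, 1, 10 and 2), with 4 interaction lists (7). By construction, leaving out genes near the loci gave 0 calls for FGF21 KO in iWAT, 1 in muscle, and 3, 0, 3 and 0 in hypothalamus in the order above, 2 lists for FGF21 KO in BAT and 100% equal signs of FGF21 loss there; leaving out Ucp1 and Fgf21 gave 0 calls for FGF21 KO in iWAT. With a 20 Mb window the BAT shares near Ucp1 were 62.1% for UCP1 KO against WT (Fisher's exact p = 0.762) and 63.1% for dKO against FGF21 KO (p = 0.106), and near Fgf21 0.301% for FGF21 KO (p = 0.0652; 70.5%, 71.3% and 0.69% at 10 Mb).

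Leave-one-out ranges for calls in the order FGF21 KO against WT, dKO against UCP1 KO and interaction were 1 to 14, 99 to 523 and 0 to 4 in BAT; for the first and second of these 1 to 2 and 3 to 6 in iWAT, and 0 to 16 and 0 to 3 in hypothalamus, where the interaction gave 0 to 7 and dKO against WT 5 (without dKO replicate 1) to 14; for FGF21 KO in muscle 0 to 3. The libraries behind them stand beside each comparison of the report. Lists ranged for FGF21 KO from 2 (without WT replicate 2) to 8 (FGF21 KO replicate 1; 7 without replicate 4) in BAT, 3 (WT replicate 2 or 3) to 10 in iWAT and 3 (WT replicate 4) to 7 in muscle; for dKO against UCP1 KO from 5 (dKO replicate 4) to 17 in iWAT, 4 to 9 (UCP1 KO replicate 5) in muscle and 4 (dKO replicate 3) to 10 in hypothalamus; for the interaction from 8 (FGF21 KO replicate 3; 10 without dKO replicate 4 or 5) to 17 in iWAT and 2 to 7 (WT replicate 1; 6 without UCP1 KO replicate 3, 5 without WT replicate 3, UCP1 KO replicate 1 or dKO replicate 3) in muscle; and for dKO against WT from 1 (dKO replicate 5) to 8 in hypothalamus. Equal signs of UCP1 loss ranged from 98.44% to 99.14% in BAT, 98.34% to 99.6% in iWAT and 95.55% to 98.35% in muscle, and of FGF21 loss in BAT from 50% (without UCP1 KO replicate 3) to 100% (WT replicate 2 or 3). No fit of muscle left out libraries by other tissue, the interaction has no fit with fewer groups, and no mitochondrially encoded gene was measured to leave out. No paired analysis was made, because the labels do not say which libraries share a mouse. By order of deposit, Nnt in muscle and hypothalamus was high in UCP1 KO replicates 1, 5 and 6 and dKO replicates 1 and 4. It was low in FGF21 KO replicate 4. This hints, from 1 gene, that the order follows the mice.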

Other observations

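Of these tests the splits for UCP1 KO against WT in BAT were chosen only after the result was seen. Each comparison was refitted to 100 splits of its samples into groups of the same sizes, the real split included. For UCP1 KO against WT the real split alone gave as many calls (1 of 100) in each tissue, arguing against chance. BAT had 9634 calls against at most 7642 in another split, and iWAT 7759 against 2933. Muscle had 1860 against 219 and hypothalamus 10 against 1. For dKO against WT this was so with 9469 against 7833, 6192 against 3223 and 1558 against 516 in BAT, iWAT and muscle. In hypothalamus 2 of 100 splits gave as many, another calling 11 against 10 (5 without dKO replicate 1), so the count leaves chance open. Scoc, Mri1, Wdr83os, Il15, Mir709 and Hook2 were also called lower for UCP1 KO against WT and dKO against FGF21 KO, which share no library. This argues against chance for them (Hook2 least, -0.26 in both). For dKO against UCP1 KO in iWAT the real split alone gave as many calls (1 of 100, 6 against 0, 3 without single libraries). The splits argue against chance for the called genes other than the knocked-out Fgf21 itself. In muscle 0 were called, so all 100 splits gave as many (highest 2) and the count says nothing about chance. In BAT the real split alone gave as many (1 of 100, 278 against 115), which argues against chance. The count was 99 without UCP1 KO replicate 3 and 50 without the libraries with skeletal muscle genes, smaller fits not comparable with 115. For FGF21 KO against WT chance cannot be excluded in BAT (8 of 100, 4 against 48). Nor can it, for the count of calls, in iWAT (13 of 100, 1 against 6350). The 1 iWAT gene is the knocked-out Fgf21 itself, with 0 to 1 counts in FGF21 KO and 9 to 26 in WT libraries, a loss that the split count does not bear on. For 3 small counts under 5 of 100 splits gave as many, but each falls to 0 without single libraries. These are FGF21 KO against WT in muscle (3 of 100, 3 against 48) and hypothalamus (1 of 100, 1 against 0). The last is dKO against UCP1 KO in hypothalamus (2 of 100, 2 against 3). Rasip1 lay at -0.81 and -0.80 (SE 0.12 each) in these hypothalamus comparisons, which share no library, and this argues against chance for it. For the other called genes chance is not taken as excluded. The 20 comparisons were not corrected for their number. For the interaction, with 0 calls in each tissue, all 100 splits gave as many by construction, with at most 15, 269, 1 and 20 in BAT, iWAT, muscle and hypothalamus.

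Splits that call several times the real count point to a structure of the samples other than genotype. In the iWAT split of WT and FGF21 KO with 6350 calls, 5 of 6 libraries on one side and 1 of 5 on the other held lymphocyte genes, against 4 of 6 and 2 of 5 in the real split. In the BAT split of these genotypes with 48 calls, 0 of 5 and 3 of 5 had skeletal muscle genes at a mean log2 CPM over 7, against 1 and 2 in the real split. For the muscle split with 48 calls and the interaction splits this was not examined.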
